A study of Homo sapiens with 6 samples.

How the data were processed

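Total RNA of cultured SCC13 cells, an established line of human squamous cell carcinoma, was sequenced after infection with the control hairpin SHC2 or with 1 of 2 hairpins against HOPX, per the labels. The 6 libraries form 3 groups of 2, and the labels place 1 library of each group in each of 2 knockdown experiments. The values used are the deposited raw counts per gene as the authors made them, and HISAT2 (2.1.0) and Salmon (0.8.2) are listed per the submitters' processing notes without their roles. The genome build, the annotation, the counting tool and the use of strand are not given in the sources used here. Of 60279 gene identifiers 56590 (93.9%) matched GENCODE 29, which served for names, gene types, exon lengths and 3' untranslated regions only, and the unmatched identifiers held 0.0612% of counts. Antisense and overlapping genes, and near-identical copies such as KRT6A, KRT14 and KRT16 with their pseudogenes, SAA1 and SAA2, S100A7 and S100A7A, and the ribosomal protein genes, may share reads, so their levels are uncertain.

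Library totals ran from 27669654 counts in H1 of experiment 1 to 32872972 counts in H2 of experiment 2. Counting error is therefore small for most genes, and the spread between the 2 libraries of a group sets the precision. HOPX itself had from 2 to 222 counts per library.

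Counts were analysed in R (4.3.3) with edgeR (4.0.16). Genes were kept by filterByExpr on the group, which left 16040 genes, and libraries were scaled by TMM. The unpaired fit held a term per group with 3 residual degrees of freedom, and the paired fit also held the experiment as a replicate block, with 2 residual degrees of freedom. Before the data were examined the unpaired fit was set as the first choice and the replicate block as an alternative. The 4 contrasts were the mean of both hairpins against control, H1 against control, H2 against control and H2 against H1, each tested over all genes by the quasi-likelihood F test with Benjamini-Hochberg adjustment and an adjusted p of 0.05 as threshold. Both fits are reported, since the pairing moved the counts of calls. The pairing was checked by the correlation over genes of the difference between experiments, with r = 0.562 between control and H1, 0.556 between control and H2 and 0.559 between H1 and H2. The 3 other ways to pair the libraries called 0 genes in each contrast.

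Genes were named by a rule set before the data were examined. HOPX came first. For the mean of both hairpins the rule took the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 5 CPM, the same direction against the control of the same experiment in all 4 knockdown libraries, and a symbol that is not a clone or pseudogene name. For the other contrasts it took 6 of each. Fewer were named where fewer passed. The same rule was applied to the paired fit, a choice made after the counts of calls were seen.

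Of 33 gene lists written in advance, with 839 of 839 entries matched, the 30 with at least 5 tested members were tested by camera of limma (3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The Benjamini-Hochberg adjustment ran over the 120 tests of 30 lists and 4 contrasts. Camera with an estimated correlation and the rotation test fry were alternatives. With an estimated correlation camera rests on the residual degrees of freedom, 3 or 2 here, so it has little power. A list call lost there is no evidence of no change. From each list up to 4 called members with the smallest p are named, or 2 as values, and a few results for single genes are not reported here. The melanocyte, the endothelial and immune, and the Merkel and sweat gland markers had fewer tested members and are given by gene.

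The genes called with both hairpins were compared with the overlap of independent lists and with 40 simulations in which the groups do not differ but share the controls. Alternatives were DESeq2 size factors, library size only, no filter, a minimum of 1 CPM in 2 libraries, DESeq2 (1.42.0), limma-voom, a fit of only the groups compared, leaving out mitochondrial and ribosomal protein genes before normalization, and leaving out each library in turn. With a library left out, the lone sample of its group was assumed to vary like the other groups.

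The fits were tested on simulated data with 16036 genes, where the contrast of the mean of both hairpins held 100 genes changed by each log2 size. The counts were drawn once, from the means and spread of the paired fit, and only genes above a minimum mean count were changed. The simulation therefore favours the paired fit and does not cover changes in genes with low counts. The unpaired fit recovered 0% of genes changed by 1 on the log2 scale and 30% of those changed by 2, and called 0 unchanged genes. With the replicate block the paired fit recovered 71% and 97%, and called 19 unchanged genes. A count of few calls in the unpaired fit is thus no evidence of no change. Tables and figures were made with Python (3.11.15), numpy (2.4.6), pandas (2.3.3) and matplotlib (3.10.9).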

Results

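Gene expression was measured by RNA sequencing in SCC13, a human squamous cell carcinoma line, after infection with a control hairpin (SHC2) or with 1 of 2 short hairpin RNAs against HOPX, shRNA-502 (H1) and shRNA-358 (H2). Each of the 3 groups held 2 libraries, 1 from each of 2 knockdown experiments. In experiment 1 the total count was 30546118 for control, 27669654 for H1 and 31885220 for H2. In experiment 2 the total was 30746326 for control, 28032846 for H1 and 32872972 for H2. The libraries of a group differed far beyond counting error, with a chi-square per degree of freedom over genes of 185 in control, 183 in H1 and 226 in H2. Fold changes and list medians come from a fit without the experiment as a term (the unpaired fit) unless stated. Fold changes of single list members against control come mostly from a fit with the experiment as a block (the paired fit). Calls are also given from the paired fit where they changed. The unpaired fit estimated a biological coefficient of variation of 0.349, against 0.196 in the paired fit with its replicate block.

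HOPX (ENSG00000171476), which encodes a small homeodomain protein that does not bind DNA itself, was lower in all 4 knockdown libraries than in both controls. It had 214 counts in control, 16 with H1 and 5 with H2 in experiment 1, and 222, 2 and 4 counts in experiment 2. The mean level was 7.18 ± 0.608 CPM in control (SD, n = 2), 0.320 ± 0.342 CPM with H1 and 0.133 ± 0.00817 CPM with H2, which is 95.5% and 98.1% lower than control. The log2 fold change of HOPX was -4.45 (SE 0.79) with H1 and -5.71 (SE 0.86) with H2. Unpaired, these gave an adjusted p of 0.0795 and 0.0570 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, above the threshold of 0.05. With the experiment as a replicate block, edgeR gave log2 fold changes of -4.54 (adjusted p = 0.00563) and -5.76 (adjusted p = 0.00319), both past the threshold. Between H2 and H1 HOPX differed by a log2 value of -1.26 (SE 0.86, edgeR adjusted p = 0.358), not past the threshold. HOPX shares its locus with overlapping annotation, and whether the counting used strand is not given in the sources used here.

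**Figure D1:**
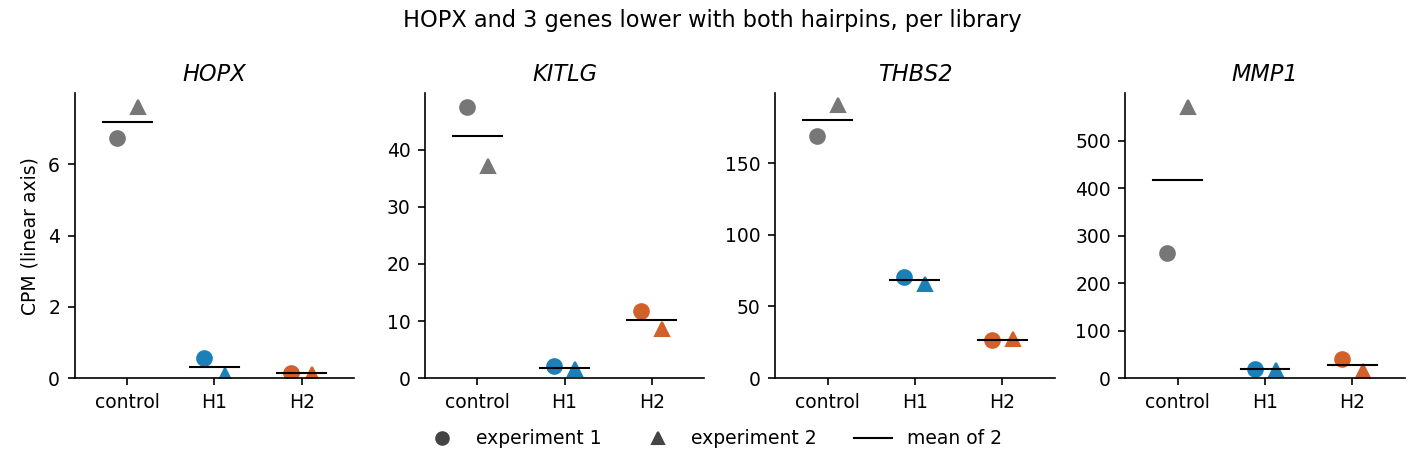
CPM per library of HOPX, KITLG, THBS2 and MMP1 in control, H1 and H2 cells, with circles for experiment 1, triangles for experiment 2 and a line at the mean of the 2 libraries. Mean HOPX was 7.18 CPM in control, 0.320 CPM with H1 and 0.133 CPM with H2, and all 4 genes were lower in every knockdown library than in both controls.

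The mean of both hairpins against control addressed which genes change when HOPX is knocked down by either hairpin. KITLG, which encodes the ligand of the KIT receptor, fell by 3.29 on the log2 scale (SE 0.24), from 42.4 ± 7.33 CPM in control to 1.84 ± 0.281 CPM with H1 and 10.2 ± 2.29 CPM with H2 (SD, n = 2 each). THBS2, which encodes the matrix protein thrombospondin 2, fell by 2.07 (SE 0.14), from 180 ± 15.0 CPM to 68.3 ± 3.54 CPM and 26.8 ± 0.755 CPM. Both were lower in all 4 knockdown libraries. They were the only 2 of 16040 genes past the threshold in the unpaired fit, each with an adjusted p of 0.0492 by edgeR's quasi-likelihood test, and 2490 genes had an unadjusted p under 0.05, 928 of them higher. Without control replicate 1 the unpaired count was 13, and without control replicate 2 or any H1 or H2 library it was 0. The paired fit, with its replicate block, gave 1782 genes by edgeR, 645 higher and 1137 lower, among them KITLG (adjusted p = 0.000502) and THBS2 (adjusted p = 0.00113).

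With the mean of both hairpins in the paired fit, collagenase and stromelysin genes were among the largest decreases. MMP1 fell by 4.25 (SE 0.43), from 418 ± 217 CPM in control to 18.2 ± 0.708 CPM with H1 and 27.8 ± 18.7 CPM with H2 (SD, n = 2 each), and MMP10 fell by 3.94 (SE 0.34). CA12, a carbonic anhydrase of the cell surface, fell by 5.12 (SE 0.36), and the receptor phosphatase gene PTPRZ1 fell by 4.37 (SE 0.32). KRT13, a keratin of stratified mucosal epithelium, had a log2 fold change of -4.72 (SE 0.55). The other named decreases were NPR3, FAM131B, ACKR3, BGN, CKB, KITLG and AKR1B10, with log2 fold changes from -4.22 for NPR3 to -3.12 for AKR1B10. Increases included the MAPK phosphatase DUSP5 at 2.37 (SE 0.21), from 14.4 CPM in control to 69.8 CPM with H1 and 88.2 CPM with H2, and the tight junction gene CLDN4 at 2.27 (SE 0.18). The remaining named increases were TMPRSS11F at 3.46, SAA2 at 3.03 (SE 0.26), BIRC3 at 2.57, CCL20 at 2.55, S100A8 at 2.31, ADAM8 at 2.55, ANKRD22 at 2.53, SRPX2 at 2.33, C15orf48 at 2.29 and ACER2 at 2.28. Some of the means lean on a single hairpin. In control, H1 and H2, S100A8 stood at 34.7, 50.8 and 436 CPM and C15orf48 at 1.22, 2.42 and 20.8 CPM, so H2 carried most of both. AKR1B10 stood at 73.3, 4.77 and 37.6 CPM, so H1 carried most of its decrease. With the replicate block the adjusted p by edgeR was 0.00393 for MMP1, 0.00274 for DUSP5 and 0.00248 for SAA2, whereas in the unpaired fit KITLG alone of these 24 genes was past the threshold. CCL20 (log2 1.49) and C15orf48 (log2 1.53) were no longer called without control replicate 2, and the count of calls fell from 1782 to 707 without it and to 1114 without H2 replicate 2. SAA2 may share reads with the near-identical SAA1.

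Among gene lists fixed before the data were examined, inflammatory genes had a higher and basal keratinocyte genes a lower median with the mean of both hairpins. The list of NF-kB targets and inflammatory cytokines had a median log2 fold change of 0.98 over 27 genes, with SAA1 at 2.01 and NFKB2 at 1.06 in the paired fit. The basal keratinocyte and hemidesmosome list had a median of -0.50 over 21 genes, with KRT15 at -2.70, KRT14 at -2.48 and the integrin gene ITGA2 at -1.36. The TGF-beta and BMP response (median -0.67), with BMP7 at -2.40, and the mesenchymal and invasion list (median -0.50), with LOXL2 at -1.41 and PDPN at -1.35, were also lower. The NRF2 list (median -0.42), with the glutathione synthesis gene GCLC at -1.32, the glycolysis and hypoxia list (median -0.32), with CA9 at -1.80, and the cytosolic ribosomal proteins (median -0.24) were lower as well. Unpaired, limma's camera called these 7 lists, with adjusted p = 0.0105 for NF-kB, 0.00327 for the basal list, 0.0337 for TGF-beta and BMP, 0.0206 for the mesenchymal list, 0.0269 for NRF2, 0.0489 for glycolysis and 3.56e-05 for ribosomal proteins. With an estimated correlation limma's camera gave each of the 7 an adjusted p = 0.915 (0.863 with the replicate block), so none passed the threshold there. With the replicate block limma's camera no longer called the mesenchymal list (adjusted p = 0.0584), and it gained 3 others. These were the interferon list (median -0.75, limma's camera adjusted p = 0.0140) and the unfolded protein and integrated stress list (median -0.37, adjusted p = 0.0217) as lower, and the ERBB and MAPK feedback list (median 0.38, adjusted p = 0.00900) as higher. For each of the 3 limma's camera gave an adjusted p = 0.863 with an estimated correlation. The interferon value leans on control replicate 2, since the list stood 2.42 higher in experiment 2 than in experiment 1 in control, against 0.37 with H1 and 0.54 with H2. The ribosomal protein median was 0.09 with H1 and -0.53 with H2. With the replicate block limma's camera called the basal list with each hairpin alone, though not with an estimated correlation. In the unpaired fit none of the 7 lists was called with each hairpin alone. With H1 limma's camera gave an adjusted p = 0.411 for NF-kB, 0.0706 for the basal list, 0.663 for TGF-beta and BMP, 0.336 for the mesenchymal list, 0.433 for glycolysis and 0.480 for ribosomal proteins, and with H2 0.497 for NRF2.

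Counted by gene with the replicate block, the paired fit called 8 NF-kB genes higher and 2 lower (11 and 3 adjusted over the list alone), and 7 basal genes lower (11 adjusted over the list alone). It called 5 lower TGF-beta and BMP genes (6 adjusted over the list alone), 8 lower and 4 higher mesenchymal genes (11 and 5 adjusted over the list alone) and 10 lower and 1 higher glycolysis genes (11 and 2 adjusted over the list alone). It called 7 lower and 1 higher NRF2 genes (11 and 2 adjusted over the list alone) and 5 lower ribosomal protein genes (5 adjusted over the list alone). In control, H1 and H2, RPS16 stood at 513, 230 and 326 CPM and RPL18 at 346, 185 and 238 CPM, while RPLP0 stood at 2699, 3222 and 503 CPM, with no decrease with H1. In the stress response list 7 genes were lower, led by the serine synthesis genes PHGDH at -2.45 and PSAT1 at -2.09, and 2 higher (14 and 4 adjusted over the list alone). In the interferon list 2 genes were lower and 1 higher (0 and 1 adjusted over the list alone). In the ERBB and MAPK list 9 genes were higher, DUSP5 and EPHA2 among them, and 2 lower (9 and 4 adjusted over the list alone). The unpaired fit by edgeR called 0 members of these lists. Over all 16040 genes 2490 had an unadjusted p under 0.05 and DESeq2 called 1011 and limma-voom 0. Without control replicate 1 limma's camera no longer called NF-kB (adjusted p = 0.469), glycolysis (0.353) or NRF2 (0.153), and without control replicate 2 it no longer called the basal list (0.0611), TGF-beta and BMP (0.962) or the mesenchymal list (0.567). Calls were also lost without H1 replicate 1 for the mesenchymal list (limma's camera adjusted p = 0.0796), without H1 replicate 2 for glycolysis (0.121), and without H2 replicate 2 for NF-kB (0.0748) and NRF2 (0.0763).

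H1 against control addressed the changes seen with the shRNA-502 hairpin alone. TMEM184B, a membrane protein gene, fell by 2.95 (SE 0.20), from 89.4 ± 7.17 CPM in control to 11.6 ± 0.313 CPM with H1 (SD, n = 2 each), and stood at 138 ± 14.7 CPM with H2. MTPN, which encodes the actin regulator myotrophin, fell by 2.47 (SE 0.19), from 272 CPM to 48.9 CPM, and TEX261, a protein of vesicle transport, by 2.65 (SE 0.23). With H2, MTPN stood at 261 CPM, and TEX261 at 68.9 CPM against 69.1 CPM in control. KITLG fell by 4.52 (SE 0.33), TMEM250 by 2.64 (SE 0.27) and BRD3OS, a transcript that lies opposite BRD3 and may share its reads, by 2.27 (SE 0.22). Without the experiment as a term edgeR's quasi-likelihood test called 14 genes, all lower in both H1 libraries, with adjusted p = 0.0364 for KITLG, TMEM184B and MTPN, and 3161 genes had an unadjusted p under 0.05. The count was 8 without control replicate 1 and 0 without control replicate 2 or any H1 or H2 library. The paired fit, with its replicate block, called 2568 genes by edgeR, 1075 higher and 1493 lower, 856 without H1 replicate 2 and 1359 without control replicate 2. There the named increases were BIRC3 at 3.14, the cell cycle gene ZNF367 at 3.03, the antimicrobial RNASE7 at 2.93, LAPTM5 at 2.92, SAA2 at 2.88 and the cytokine TNFSF9 at 2.81. The named decreases were KRT13 at -6.10, MMP10 at -4.89, FAM131B at -4.88, CLU at -4.82, AKR1B10 at -4.57 and MMP1 at -4.54, none of these 12 past the threshold in the unpaired fit.

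With H1, replication genes had a higher and interferon-stimulated genes a lower median. The S phase list had a median log2 fold change of 0.65 over 29 genes, with the replication licensing gene CDC6 at 1.45 and the cyclin gene CCNE2 at 2.40 in the paired fit. ERBB and MAPK feedback genes had a median of 0.48, with DUSP6 at 2.35, FOSL1 at 2.16 and SPRY4 at 1.77, and cholesterol synthesis genes a median of 0.32, with INSIG1 at 1.89. The type I interferon list had a median of -1.52 over 44 genes, with SAMD9L at -1.92, and the NRF2 list a median of -0.32, with AKR1C3 at -3.84. Unpaired, limma's camera called these 5 lists, with adjusted p = 0.000184 for S phase, 0.0076 for ERBB and MAPK, 0.0497 for cholesterol, 0.0025 for interferon and 0.0121 for NRF2. These 5 calls too were lost with an estimated correlation, where limma's camera gave an adjusted p = 0.915 (0.863 with the replicate block). The interferon difference rested on control replicate 2, where IFIT1 stood at 302 CPM against 22.4 CPM in control replicate 1 and 9.39 and 14.9 CPM with H1. Without that control the list's direction reversed (limma's camera adjusted p = 0.574), and without H1 replicate 1 the adjusted p was 0.0773. Gained with the replicate block by limma's camera were the cornified envelope list (adjusted p = 0.0108) and the basal list (median -0.69, adjusted p = 0.0157) as lower, and the differentiation transcription factors (median 0.46, adjusted p = 0.0190) and the G2 and mitosis genes (median 0.38, adjusted p = 0.00303) as higher. These 4 as well were lost with an estimated correlation (limma's camera adjusted p = 0.863). Without control replicate 1 cholesterol (limma's camera adjusted p = 0.288), NRF2 (0.0608) and ERBB and MAPK (0.212) were no longer called, nor without H1 replicate 2 were cholesterol (0.249) and ERBB and MAPK (0.0711).

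By gene, the paired fit with its replicate block called 13 S phase genes higher with H1 (16 adjusted over the list alone), 9 ERBB and MAPK genes higher and 1 lower (the same numbers adjusted over the list alone), and 6 cholesterol genes higher and 1 lower (10 and 1 adjusted over the list alone). It called 15 interferon genes lower (23 lower and 1 higher adjusted over the list alone) and 9 NRF2 genes lower and 1 higher (10 and 1 adjusted over the list alone). In the keratinocyte lists it called 6 cornified envelope genes lower, KLK13 at -4.13 and SBSN at -3.92 among them, and PPL higher at 1.11 (11 and 1 adjusted over the list alone). KLK13 and SBSN had low counts, with means of 3.64 and 6.49 CPM in control and 0.174 and 0.35 CPM with H1. For both genes the SD in control (n = 2) exceeded the mean, at 4.93 CPM for KLK13. Most of each control mean therefore came from 1 library, and the size of these 2 decreases is uncertain. The paired fit called 7 basal genes lower, led by KRT15 at -4.01, and 1 higher (10 and 1 adjusted over the list alone). It called the differentiation factors TFAP2C and KLF4 higher (2 adjusted over the list alone). Of the G2 and mitosis genes 5 were higher, UBE2C and ANLN among them (5 adjusted over the list alone).

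H2 against control addressed the changes seen with the shRNA-358 hairpin alone. PTBP2, a splicing regulator, rose by 2.64 (SE 0.20), from a mean of 18.8 CPM in control to 117 CPM with H2. DNAJC12, a cochaperone, rose by 3.86 (SE 0.35), from 0.935 CPM to 13.7 CPM, and ETV1, TULP3, MANSC1 and TSPAN6 rose by 2.36, 2.36, 2.26 and 1.87. HDAC3, which encodes a class I histone deacetylase, fell by 2.73 (SE 0.24), from 92.1 ± 16.1 CPM to 13.8 ± 2.32 CPM (SD, n = 2 each), and stood at 94.7 CPM with H1. Log2 fold changes were -5.90 (SE 0.69) for CA12, -5.63 (SE 0.61) for the natriuretic peptide receptor gene NPR3, -4.35 (SE 0.49) for PTPRZ1, -3.62 (SE 0.41) for the lysosomal protease gene CTSB and -2.74 (SE 0.19) for THBS2. In the unpaired fit edgeR's quasi-likelihood test called 49 genes, 7 higher and 42 lower in both H2 libraries, with adjusted p = 0.0422 for PTBP2, DNAJC12, HDAC3 and THBS2, and 3264 genes had an unadjusted p under 0.05. The count was 0 without any 1 of the 6 libraries, controls included, and 7 with mitochondrial and ribosomal protein genes left out before normalization. Paired by experiment, with the replicate block, edgeR called 2891 genes, 1275 higher and 1616 lower (1536 and 1401 with library size only), 1477 without H2 replicate 1 and 918 without H2 replicate 2. Its named increases were APOBEC3A at 4.36, TMPRSS11F at 4.34, DNAJC12 at 3.86, TNFSF18 at 3.83, C15orf48 at 3.65 and PDZK1IP1 at 3.55, and its named decreases CA12 at -6.01, NPR3 at -5.71, BGN at -4.67, NPNT at -4.35, PTPRZ1 at -4.26 and MMP1 at -3.96. APOBEC3A (log2 3.05) was not called without H2 replicate 2, and PDZK1IP1 not without control replicate 2 (log2 0.35) or H2 replicate 2 (log2 1.52).

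With H2, ribosomal protein, stress response and TGF-beta genes had lower medians and inflammatory genes a higher one. The 66 cytosolic ribosomal protein genes had a median log2 fold change of -0.53, and -0.52 with DESeq2 size factors and -0.43 with library size only, and RPLP0 fell by 2.42. Many of these genes have near-identical pseudogenes that can take their reads. The unfolded protein and integrated stress list had a median of -0.73, with TRIB3 at -2.04 and ASNS at -1.40 in the paired fit, and the TGF-beta and BMP list -1.21, with INHBA at -2.17. Medians were -0.95 for the mesenchymal list, -0.86 for WNT, with the cyclin gene CCND1 at -1.65, -0.50 for S phase, with TYMS at -2.41, -0.46 for glycolysis, -0.45 for cholesterol and -0.42 for the basal list, with KRT5 at -3.00. NF-kB targets had a median of 1.44, with the chemokine gene CXCL1 at 3.20 and PTGS2 at 1.92. Of the 30 lists limma's camera called these 10 in the unpaired fit, with adjusted p = 1.42e-12 for ribosomal proteins, 0.00265 for both TGF-beta and the stress response, 0.0108 for mesenchymal, 0.0340 for WNT, 0.0489 for S phase, 0.0145 for glycolysis, 0.0121 for cholesterol, 0.0076 for basal and 0.00327 for NF-kB. None of the 10 held with an estimated correlation, where limma's camera gave an adjusted p = 0.915 (0.863 with the replicate block). With the replicate block limma's camera also called the G2 and mitosis list as lower (median -1.08, adjusted p = 9.04e-09) and the MHC list (median 0.53, adjusted p = 0.0123) and mitochondrially encoded genes (median 0.49, adjusted p = 0.0140) as higher. All 3 had a limma's camera adjusted p = 0.863 with an estimated correlation.

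By gene, the unpaired fit called 2 ribosomal protein genes lower with H2 (2 adjusted over the list alone). The paired fit with its replicate block called 18 ribosomal protein genes lower and 0 higher (27 and 0 adjusted over the list alone). It called 12 stress genes lower and 2 higher (17 and 3 adjusted over the list alone), 10 TGF-beta genes lower (11 lower and 1 higher adjusted over the list alone) and 11 mesenchymal genes lower and 3 higher (13 and 5 adjusted over the list alone). It called 6 WNT genes lower and 1 higher (7 and 1 adjusted over the list alone), 6 S phase genes lower (7 adjusted over the list alone) and 11 glycolysis genes lower, the glucose transporter gene SLC2A1 among them, while SLC2A3 rose by 3.43 (14 and 1 adjusted over the list alone). It called 3 cholesterol genes lower and 1 higher (the same numbers adjusted over the list alone), 7 basal genes lower (9 adjusted over the list alone) and 15 NF-kB genes higher and 2 lower (18 and 2 adjusted over the list alone). Of the G2 and mitosis genes 16 were lower, CDC20 and AURKB among them (23 adjusted over the list alone), HLA-B was the 1 MHC gene called, at 1.37 (1 adjusted over the list alone), and MT-ND3 the 1 mitochondrial gene (0 adjusted over the list alone). Without control replicate 1 limma's camera no longer called S phase (adjusted p = 0.382), NF-kB (0.116) or glycolysis (0.112). Without control replicate 2 it no longer called the basal list (limma's camera adjusted p = 0.0674), TGF-beta (0.0821), WNT (0.0728), mesenchymal (0.213), cholesterol (0.158) or the stress response (0.0728). Without H2 replicate 2 it no longer called S phase (limma's camera adjusted p = 0.0839), NF-kB (0.314) or cholesterol (0.139).

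The overlap of H1 and H2 addressed which genes changed with both hairpins. MMP1, KITLG, THBS2, CA12 and PTPRZ1 were lower with both, and DUSP5, CLDN4 and SAA2 higher with both. Paired, with the replicate block, 534 genes were called with both hairpins in the same direction, 248 higher and 286 lower, and 182 in opposite directions. Independent lists of these sizes would share 85.5 higher and 150 lower genes, and 40 simulations of unchanged groups against the same controls gave a mean of 0.275 genes called with both and at most 3. In the unpaired fit edgeR called 0 genes with both hairpins, while 635 had an unadjusted p under 0.05 with both in the same direction, 284 higher and 351 lower, and 250 in opposite directions. There DESeq2 called 255 genes with both and limma-voom 0, and independent lists would share 0.0367 lower genes. Across genes, which are not independent replicates, the log2 fold changes of H1 and H2 had a correlation of 0.202 and a covariance of 0.177, beside 0.494 and 0.0889 in the simulations, a difference in covariance of 0.0877. The sign was the same for 53.7% of genes, beside 66.6% in the simulations. The simulated groups held no hairpin effect, and effects particular to a hairpin lower both the correlation and the share of equal signs. These 2 values therefore do not show that the hairpins agree less than unchanged groups. Groups with separate hairpin effects were not simulated. The 2 controls cannot be split, so part of the excess in shared calls and in covariance may come from the shared controls. In the paired fit the 534 shared calls became 277 without control replicate 2, 883 without control replicate 1, 303 without H1 replicate 2 and 233 without H2 replicate 2.

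H2 against H1 addressed which genes differ between the hairpins. GLIPR1, a secreted protein gene of the pathogenesis-related family, was higher with H2 by 5.57 (SE 0.71), at 46.8 ± 22.8 CPM with H2, 0.980 ± 0.00539 CPM with H1 and 8.90 ± 6.43 CPM in control (SD, n = 2 each). CFI, which encodes complement factor I, was higher by 5.10 (SE 0.54), POF1B by 5.25 (SE 0.69), TNFSF18 by 5.17, the myosin light chain gene MYL9 by 4.29 and MLLT11 by 4.22. SFRP1, a secreted WNT antagonist, was lower with H2 by a log2 value of -3.93 (SE 0.47), at 3.14 CPM with H2, 47.9 CPM with H1 and 31.4 CPM in control. SCD, a fatty acid desaturase gene, had a log2 difference of -3.92 (SE 0.65), VSTM2L -4.78 (SE 0.51), MN1 -4.54, SERPINE2 -4.28 and LAPTM5 -4.07. In the unpaired fit edgeR's quasi-likelihood test called 1648 genes, 885 higher and 763 lower with H2, with adjusted p = 0.0191 for GLIPR1, 0.0151 for CFI and 0.0177 for SFRP1. With library size only, which moved the median of all genes to 0.106, 64.6% of the calls were higher with H2, against 53.7%. The count was 830 without control replicate 1, 589 without control replicate 2 and 0 without any H1 or H2 library. The paired fit with its replicate block called 5661 genes by edgeR, 2842 higher and 2819 lower (3295 and 2310 with library size only), 3337 without H2 replicate 1, 2960 without H2 replicate 2 and 3180 without H1 replicate 2. Its named genes were APOBEC3A at 6.87, S100A7A at 6.02, GLIPR1, POF1B, GPX2 at 5.11 and CFI as higher, and VSTM2L, MN1, SCD, SFRP1, LAPTM5 and SH2D5 at -3.92 as lower. S100A7A, which may share reads with S100A7, was not called without H1 replicate 2 (log2 4.50) or H2 replicate 2 (log2 1.56).

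Between the hairpins, replication and ribosomal protein genes had lower medians with H2 than with H1 and interferon-stimulated genes a higher one. The S phase list had a median difference of -1.10, with E2F1 at -2.96 and CDC6 at -1.82, the ribosomal proteins -0.58, and -0.58 with DESeq2 size factors and -0.46 with library size only, and the stress response list -0.72, with TRIB3 at -2.29. Cholesterol synthesis genes had a median of -0.67, with the squalene epoxidase gene SQLE at -2.10, and WNT genes -0.87, with FZD10 at -2.67, while WNT10A was higher at 3.46. Interferon genes had a median of 1.01, with CXCL11 at 3.06 in the paired fit. Unpaired, limma's camera called these 6 lists, with adjusted p = 1.53e-06 for S phase, 1.73e-09 for ribosomal proteins, 0.00265 for both the stress response and cholesterol, 0.0489 for WNT and 0.00971 for interferon. All 6 were lost with an estimated correlation, with limma's camera adjusted p = 0.915 (0.863 with the replicate block). With the replicate block limma's camera also called the G2 and mitosis (median -1.51, adjusted p = 3.12e-10), TGF-beta (median -1.12, adjusted p = 0.0139) and ERBB and MAPK (median -0.69, adjusted p = 0.00494) lists as lower with H2, and the cornified envelope (median 1.05, adjusted p = 0.0247) and mitochondrially encoded (median 0.52, adjusted p = 0.0222) lists as higher. Each of these 5 had an adjusted p = 0.863 by limma's camera with an estimated correlation. By gene, edgeR in the unpaired fit called 4 S phase genes lower (10 adjusted over the list alone), 7 ribosomal protein genes lower (7 adjusted over the list alone), 3 stress genes lower and 1 higher (the same numbers adjusted over the list alone), 7 cholesterol genes lower and 1 higher (10 and 1 adjusted over the list alone), 5 WNT genes lower and 1 higher (6 and 2 adjusted over the list alone) and 1 interferon gene higher (0 adjusted over the list alone). In the paired fit with its replicate block the lower genes were 22 of S phase, 36 ribosomal protein, 17 stress, 13 cholesterol and 8 WNT genes (25, 45, 20, 13 and 8 adjusted over the list alone). The higher genes were 16 of interferon, 2 stress, 1 cholesterol and 2 WNT genes (the same numbers, and 1 ribosomal protein gene, adjusted over the list alone). Of the lists gained, 26 G2 and mitosis, 9 TGF-beta and 12 ERBB and MAPK genes were lower and 11 cornified envelope and 5 mitochondrial genes higher (30, 9, 12, 14 and 6 adjusted over the list alone). Against the direction of their list, 1 TGF-beta and 1 ERBB and MAPK gene were higher and 1 cornified envelope gene lower (1, 1 and 2 adjusted over the list alone). Without H1 replicate 1 limma's camera no longer called WNT (adjusted p = 0.157) or interferon (0.0852), nor without H2 replicate 2 (0.0533 and 0.0759).

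**Figure D2:**
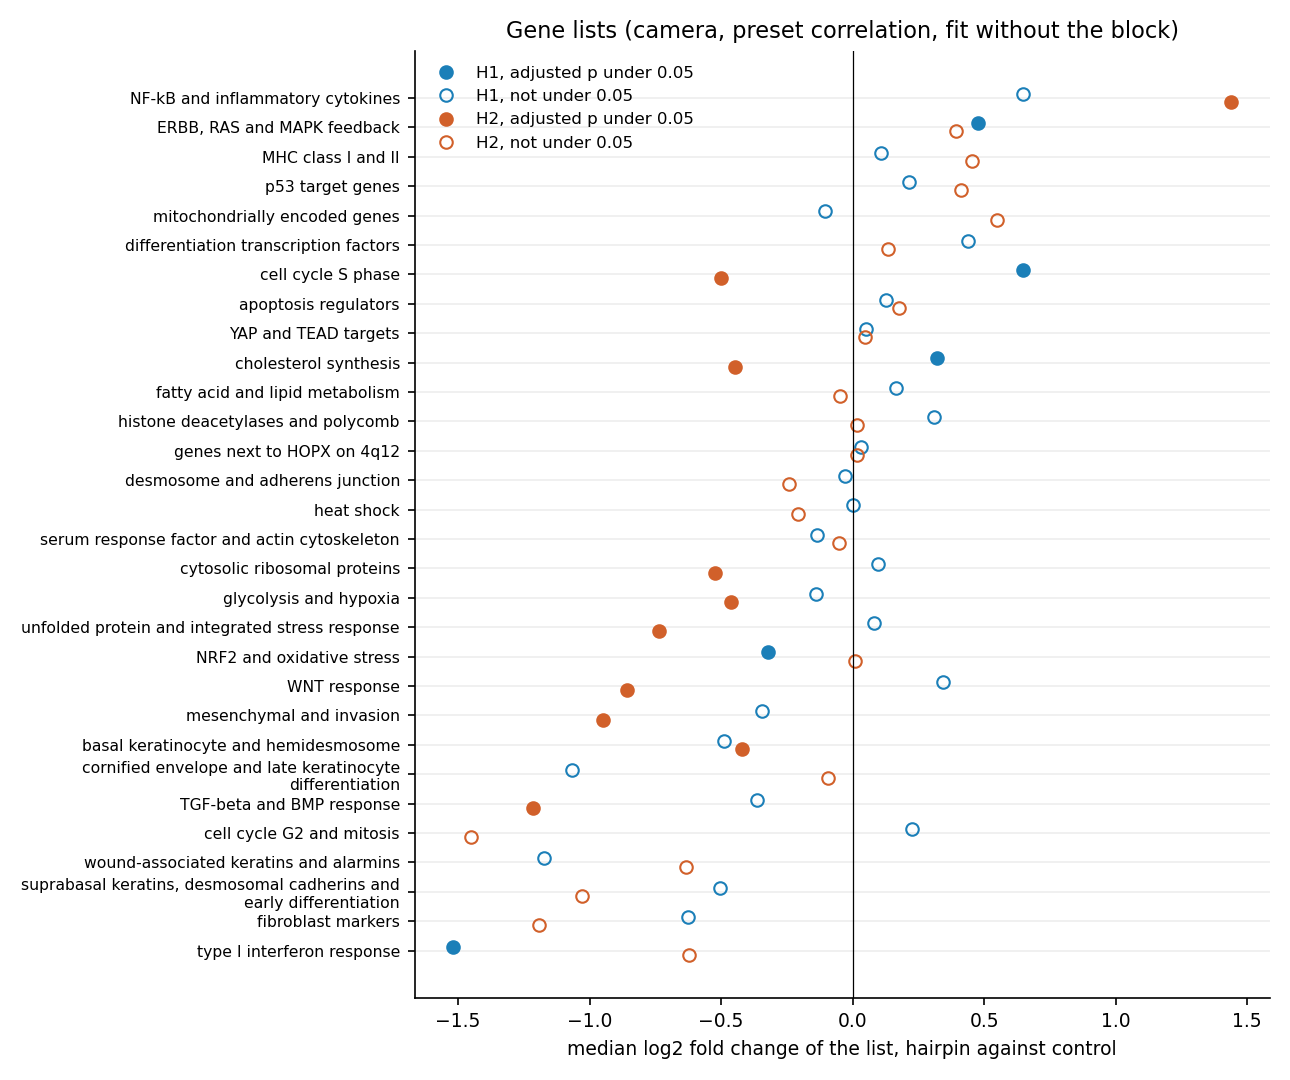
Median log2 fold change against control of each of the 30 lists with H1 (blue) and H2 (orange), with filled points for lists called by limma's camera (adjusted p under 0.05) in the unpaired fit. The S phase list lies at 0.65 with H1 and -0.50 with H2, and the cytosolic ribosomal proteins at 0.09 and -0.53.

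Of the lists that limma's camera called in neither fit, several held single genes that changed with the mean of both hairpins in the paired fit with its replicate block. NOTCH1 fell by 1.21 and the connexin gene GJB6 by 2.13 in the suprabasal and early differentiation list, where 4 genes were higher and 6 lower (5 and 9 adjusted over the list alone). The wound-associated keratins and alarmins had 2 higher, TGFA and HBEGF, and 2 lower, S100A2 and IL33 (2 and 6 adjusted over the list alone), and PKP1, a desmosomal plakophilin gene, was the 1 junction gene called, at -1.52 (1 higher and 2 lower adjusted over the list alone). The p53 targets had 7 higher, FAS at 1.13 among them, and 2 lower, TNFRSF10B among them (8 and 4 adjusted over the list alone), and the apoptosis regulators 7 higher, BCL2L11 at 1.25 among them, and 0 lower (8 and 3 adjusted over the list alone). The actin and SRF list had 6 lower, TPM1 among them (9 lower and 2 higher adjusted over the list alone), and the YAP and TEAD targets 3 higher, CYR61 at 1.23 among them, and 2 lower (5 and 3 adjusted over the list alone). The fatty acid and lipid list had 4 higher and 4 lower, CD36 at -2.86 and FABP5 at -2.34 among them (4 and 6 adjusted over the list alone), and the heat shock list 1 lower, HSP90AA1 at -0.82 (1 adjusted over the list alone). Histone deacetylases and polycomb genes had 2 higher and 2 lower, HDAC3 at -1.34 among them (2 and 2 adjusted over the list alone). H2 carried most of 3 of these means, with -2.73 for HDAC3 (0.04 with H1), -2.15 for NOTCH1 (-0.27 with H1) and, among the fibroblast markers, -1.32 for FBLN1 (-0.22 with H1). Of the genes beside HOPX, ARL9 was lower at -1.94 (3 lower and 2 higher adjusted over the list alone), and of the fibroblast markers FBLN1 at -0.77 and MMP2 at -2.13 (2 adjusted over the list alone). The lowest limma's camera adjusted p over the 4 contrasts of the unpaired fit in these 12 lists was 0.0706, for the suprabasal list.

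Many markers of other cell types did not pass the expression filter in these libraries. Of 14 fibroblast markers 7 were tested. Among them FBLN1 stood between 20.9 and 65.7 CPM, MMP2 between 4.38 and 67.4 CPM and COL1A1 between 11.8 and 21.9 CPM. COL3A1, not tested, stood at most at 0.393 CPM. Of 8 melanocyte markers MITF and PMEL were tested, with MITF at most 12.3 CPM, and MITF was higher with H1 in the paired fit by 1.52 (1 adjusted over the list alone). Of 14 endothelial and immune markers 4 were tested, with CDH5 at most 20.8 CPM, and PTPRC at most 0.0655 CPM. In the paired fit with its replicate block CD14 was higher with H2 by 1.07 (1 adjusted over the list alone). Of 10 Merkel and sweat gland markers 4 were tested, among them the simple epithelial keratin genes KRT8 and KRT18, which were both lower with H2 than with H1 in the unpaired fit, at -1.83 and -0.98 (2 adjusted over the list alone), with KRT8 between 167 and 832 CPM.

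The share of counts from mitochondrially encoded genes was 5.86% in control, 4.75% with H1 and 7.78% with H2 in experiment 1, and 13.0%, 11.7% and 18.1% in experiment 2. Cytosolic ribosomal protein genes took 6.81%, 7.08% and 5.49% in experiment 1 and 5.87%, 6.19% and 3.52% in experiment 2, so that both H2 libraries held the lowest share of their experiment. With an estimated correlation limma's camera gave every list call of the unpaired fit, 6 higher and 22 lower, an adjusted p = 0.915. It gave every list call of the paired fit, with the replicate block, an adjusted p = 0.863, so 0 of them hold there. That test rests on 3 or 2 residual degrees of freedom, and it gave all called lists of a fit the same value. A call lost there is no evidence that the list did not change, and a call with the preset correlation rests on that assumed value. The rotation test fry, which asks whether a list's genes move on balance in 1 direction, gave a lowest adjusted p of 0.446 in the unpaired and 0.261 in the paired fit. In 18 of the 120 list tests of each fit the median, mean and test differed in sign, and 0 of these were called. An example is the interferon list with H2, with a median of -0.62 and a test direction higher than other genes (limma's camera adjusted p = 0.961).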

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

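The genes and lists here were looked at again because they differ between the hairpins and, by log2 fold change for genes and by median for lists, lie on opposite sides of the control. The share of genes farther from control with H1 and the check of the pairing were chosen after the results were seen, and the other tests before. Of 61 genes named by the rule 27 differed between H2 and H1 in the unpaired fit, and 7 of them were called on opposite sides of the control in the paired fit with its replicate block.

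GLIPR1 differed by 5.57 (edgeR adjusted p = 0.0191), with -2.99 with H1 and 2.48 with H2 against control. POF1B differed by 5.25 (edgeR adjusted p = 0.0199), with -3.40 and 1.81. CFI differed by 5.10 (edgeR adjusted p = 0.0151), with -2.91 and 2.15. MLLT11 differed by 4.22 (edgeR adjusted p = 0.0222), with -2.50 and 1.69. TMEM184B differed by 3.57 (edgeR adjusted p = 0.0151), with -2.95 and 0.62. MANSC1 differed by 3.16 (edgeR adjusted p = 0.0151), with -0.90 and 2.26. VSTM2L differed by -4.78 (edgeR adjusted p = 0.0151), with 1.45 and -3.25. Among lists the S phase genes had a median difference of -1.10 (limma's camera adjusted p = 1.53e-06), with 0.65 with H1 and -0.50 with H2. The WNT response had a median difference of -0.87 (limma's camera adjusted p = 0.0489), with 0.35 and -0.86. Cholesterol synthesis had a median difference of -0.67 (limma's camera adjusted p = 0.00265), with 0.32 and -0.45. The unfolded protein and integrated stress response had a median difference of -0.72 (limma's camera adjusted p = 0.00265), with 0.08 and -0.73. The cytosolic ribosomal proteins had a median difference of -0.58 (limma's camera adjusted p = 1.73e-09), and -0.58 and -0.46 with the other scalings, with 0.09 with H1 and -0.53 with H2. For all 5 lists the adjusted p = 0.915 with an estimated correlation. With H1 against control limma's camera did not call the WNT (adjusted p = 0.400), stress response (0.663) or ribosomal protein (0.480) lists, and the mean with H1 was -0.05 for both WNT and the stress response, on the same side as with H2. For these 3 lists opposite sides are therefore not shown by a test.

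The 1648 genes that differ between H1 and H2 are the largest set of calls of the unpaired fit. A different remaining level of HOPX is argued against: 47.8% of these genes lay farther from control with H1, where an effect that scales with HOPX would put nearly all of them farther from control with the same hairpin. The test set in advance did not decide, since 9.47% of these genes were called on opposite sides of the control with the replicate block, between its bounds of 5% and 25%. With mitochondrial and ribosomal protein genes left out before normalization 1642 genes differ, so the count hardly depends on their presence. Both counts use TMM, which already trims extreme genes, so this test could hardly have come out otherwise. It does not decide whether counts taken by those genes play a part. Silencing of other transcripts by each hairpin stays open, as do differences between the infected cultures.

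The lower ribosomal protein genes with H2 (median -0.53, and -0.52 and -0.43 with the other scalings) may come from a loss of short transcripts in the H2 libraries or from a change in the cells. Other genes matched on exon length and mean expression had a median of -0.24 with H2, with a range of -0.57 to 0.05 over 1000 draws. That median lies between the bounds set in advance, so the test decides neither way. The matching was loose in kind, since the exon bases per gene (median 3332 for ribosomal protein genes and 3391 for matched genes) sum over all annotated transcripts and overstate the length of the short main transcript. No biological explanation was tested for this pattern.

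The replicate block raised the number of genes called from 2 to 1782 with the mean of both hairpins. Differences between the 2 knockdown experiments that the 3 groups share would likely give this, and the difference between experiments had r of at least 0.556 over genes between every pair of groups. The pairing named in the labels was the only one of the 4 possible to call any gene. A fit with 2 residual degrees of freedom rests on information pooled over genes, so single calls of the paired fit stay less certain than their number.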

How the results depend on the processing

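The calls depend strongly on the model. With the replicate block the counts became 1782 with the mean of both hairpins (2 in the unpaired fit), 2568 with H1 (14), 2891 with H2 (49), 5661 for H2 against H1 (1648) and 534 with both (0), because the block removes the variance shared within an experiment, and all unpaired calls were also paired calls. In that order the other settings of the unpaired fit gave 0, 6, 48, 1655 and 0 with DESeq2 size factors, 0, 0, 0, 1369 and 0 with library size only, and 1461, 1907, 1977, 3980 and 412 with no filter. They gave 0, 6, 59, 1711 and 0 with at least 1 CPM in 2 libraries, 1011, 1509, 1648, 3659 and 255 with DESeq2, and 0, 6, 27, 1626 and 0 with limma-voom. A fit of only the groups compared gave 0 with H1, 0 with H2 and 697 for H2 against H1, which leaves fewer degrees of freedom. Without mitochondrial and ribosomal protein genes the H2 count was 7. The adjusted p of KITLG and THBS2 with the mean of both hairpins was 0.0524 by edgeR with DESeq2 size factors and 0.0563 with at least 1 CPM in 2 libraries. Why the filter and the scaling move the counts so far was not shown, and the cause was not tested.

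Leaving out each library in turn, the unpaired counts ran from 0 to 13 with the mean of both hairpins, 0 to 8 with H1, 0 to 0 with H2, 0 to 830 for H2 against H1 and 0 to 0 with both. In the paired fit, with the replicate block, they ran from 707 to 2179 with the mean of both hairpins, 856 to 2882 with H1, 918 to 3604 with H2, 2960 to 6735 for H2 against H1 and 233 to 883 with both. Each such fit has 1 library in a group and 1 degree of freedom less, and the cause of the changes was not tested. With no filter the paired fit called 2825 genes with the mean of both hairpins and 884 with both. Without the replicate block its counts are the unpaired 2, 14, 49, 1648 and 0.

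The log2 fold change of HOPX with the mean of both hairpins, with H1 and with H2 was -5.15, -4.54 and -5.76 with the replicate block, -5.08, -4.45 and -5.71 with no filter and -5.10, -4.45 and -5.74 with DESeq2, all 9 past the threshold where the unpaired fit is not. With a library left out it ran from -6.09 to -4.69, from -6.47 to -3.66 and from -5.80 to -5.62. All 32 named entries of the unpaired fit lost their call with any H1 or H2 library left out.

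Of 28 list calls in the unpaired fit 0 held with an estimated correlation and 0 with fry, and of 42 with the replicate block likewise 0 and 0. The test with an estimated correlation has little power with so few residual degrees of freedom. DESeq2 size factors gave 25, without glycolysis with the mean of both hairpins, cholesterol with H1 and WNT for H2 against H1 (limma's camera adjusted p = 0.0502 each). At least 1 CPM in 2 libraries gave 23, without these 3 (limma's camera adjusted p = 0.0521, 0.0663 and 0.0521) and without S phase (0.0606) and WNT (0.0663) with H2, and with a library left out there were 29 to 44. The interferon list with H1 reversed without control replicate 2, with limma's camera adjusted p from 3.94e-25 without control replicate 1 to 0.574 without control replicate 2, and the cause was not tested. Apart from what is given here and in the report, the replicate block changed no other call. Every alternative planned was run.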

Other observations

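The 2 knockdown experiments differ in the level of G2 and mitosis genes in all 3 groups. The G2 and mitosis list was lower in experiment 2 than in experiment 1 by a median log2 value of -3.82 in control, -3.30 with H1 and -2.81 with H2. The S phase list differed by -0.42, -0.0065 and -0.17 in the same order. MKI67 stood at 463, 489 and 133 CPM in control, H1 and H2 of experiment 1, and at 24.7, 60.6 and 15.6 CPM in experiment 2. Mitochondrially encoded genes differed by 1.17, 1.65 and 1.44, and wound-associated keratins and alarmins by 1.68, 0.55 and 1.62. Interferon genes differed by 2.42 in control, 0.37 with H1 and 0.54 with H2. These differences between experiments were not tested.

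The search for short words in 3' untranslated regions was set in advance, and the search for windows of HOPX was chosen after the first results were seen. A hypothesis is that each hairpin also silences transcripts that pair with its seed, which could account for part of the genes that differ between H1 and H2. Among 16240 words of 7 bases, carriers of CACTCTC (1305 genes) fell most with H1, with t = -9.13 against a lowest of -4.93 over 100 shuffles, and 0.0815 with H2. Carriers of ACAAGGA (1503 genes) fell most with H2, with t = -9.92 against -5.20 over shuffles, and -0.642 with H1. The rule set in advance would have rejected the hypothesis for both hairpins, because neither word occurs in HOPX. That part of the rule was wrong by design, since a word that reaches past the stretch paired with HOPX can score lowest. For H1 the overlapping word GCACTCT (t = -8.21) is itself absent from HOPX, and only its reverse complement lies in a coding HOPX transcript. Another overlapping word, ACTCTCA (t = -7.50), lies in coding HOPX itself, in HOPX-202, HOPX-205 and HOPX-211 and outside the window given below. Counted on either strand, 21 of the 100 shuffles also had such a neighbour. For H2 the overlapping word AACAAGG (t = -9.70) lies in a coding HOPX transcript, but 27 of the 100 shuffles also had such a neighbour. That count therefore leaves the source of the word open for H2.

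For H1, 5 of the 10 lowest words lay on either strand in 1 window of 25 bases of coding HOPX, AGAGTGCAGATCCGTCACAGACTAA, where 100 shuffles gave at most 3. For H2 the most in a window was 1, which 92 of the 100 shuffles reached, so the window search adds nothing for H2. Overlapping words are not independent. In the H1 window ATCCGTC, TCCGTCA, CCGTCAC and CGTCACA are shifts of 1 stretch, and GCACTCT lies there only as its reverse complement. Shuffles remove such runs of words, so they do not by themselves show whether the words come from HOPX. The hairpin sequences are not given in the sources used here, so the hypothesis may hold or not for any single gene. A rescue with HOPX that the hairpins cannot target, or hairpins with other seeds, would separate these effects from those of HOPX.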
